A study of Drosophila melanogaster with 4 samples.

How the data were processed

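The series profiled RNA polymerase II phosphorylated at serine 2 of the heptad repeats of its carboxy-terminal domain, a modification carried by elongating polymerase, by chromatin immunoprecipitation and sequencing. The cells were CME-W1-Cl.8+ (Clone 8), a *Drosophila melanogaster* line labelled male and derived from the dorsal mesothoracic (wing) disc of larvae at the third instar. Per the labels' protocols, cultures were fixed with 1.8% formaldehyde for 10 min, and chromatin was incubated with antibody for 15 h. The labels name 4 samples, 2 immunoprecipitations (replicates 1 and 2) and 2 inputs. Separate input values were not analysed here. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical.

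Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are those of FlyBase release 5, per the file headers. The cluster caller, its thresholds, the treatment of the input and the way the replicates were combined are not given in the sources used here. The lists used were 1 cluster list for each immunoprecipitation and 1 list of the whole replicate set, here called the combined list, which is the authors' pooled result and has no SD or n. Each cluster has a first and last base and a score. The deposited score was read as the authors' log2 enrichment. The ground was that some differences between repeated scores within a list matched logarithms of ratios of small whole numbers, and more did so in base 2 than in other bases. Among all pairs of repeated scores in replicate 1, 237 of 26796 differences matched a ratio of whole numbers up to 14 in base 2, against 0 in natural logarithms and 3 in base 10, within 1e-08. In replicate 2 the matches were 138 of 12246, against 0 and 5, and in the combined list 167 of 8128, against 0 and 11. What the log2 enrichment is relative to is not stated. It is used to describe, rank and filter clusters, to correlate paired clusters of the replicates, and in a test between X and autosomal clusters within each list. Differences in score between lists are given as descriptions. Clusters are named enriched or depleted in the lists, with scores above and below 0.

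Sequencing depth is unknown for these lists, since they state no read numbers, and no interval below rests on a read number. Binomial intervals (exact, 95%) cover counting error over clusters only. Clusters were taken as deposited, except that 1 combined cluster on chromosome 4 ran 834 bp past the length in the header and was shortened to it. Covered shares were taken over 139.712 Mb, the lengths of 13 sequences. Those were the arms X, 2L, 2R, 3L, 3R and 4, the heterochromatic sequences 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, and the unplaced sequence U. Uextra held no cluster and was left out. The part of each sequence to which reads could be aligned was not examined, so shares are over full lengths.

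Clusters of different lists were called shared when they overlapped by 1 bp or more. The overlap of the replicates was tested against 1000 circular shifts of one list within each chromosome (one-sided; the smallest p they can give is 0.001). Correlations of scores and widths were taken over mutual best pairs, which are clusters of 2 libraries and not independent replicates, so no p is given. The covered share of X was compared with that of 2L, 2R, 3L and 3R over 100 kb bins, averaged over the replicates, by a two-sided permutation of bins (100000 permutations) with a bootstrap interval over bins (10000 resamples, 95%). Bins are not replicates, and that p covers variation along the chromosomes of these libraries. A rotation of the X block along the joined arms was added after seeing the data, because neighbouring bins resemble each other. Also added then were the comparison of log2 enrichment between X and autosomes, the removal of clusters wider than 20 kb, the minimum width for combined clusters, the removal of the widest chromosome 4 cluster, and the covered length of each replicate alone.

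The named clusters were fixed before the data were examined: the 10 combined clusters with the highest score that overlap a cluster in each replicate, the 5 widest combined clusters, the highest-scoring combined cluster of each sequence, and the 2 highest-scoring clusters of each replicate with no overlap in the other. The depleted clusters, the cluster-free stretches and the densest 500 kb bins were chosen after their values were seen. Planned analyses of genes (covered genes, profiles along genes and gene lists) were not run, because the gene table used here follows release 6 of the genome, and coordinates were not converted between releases. No cluster is therefore assigned to a gene.

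The overlap test and the X test were tested on simulated data. With no relation between lists, 7% of 200 simulated pairs gave p under 0.05. Those pairs were made by the same kind of rotation as the test's shifts, so they cannot show whether the shifts suit real lists. All 10 lists with a planted overlap, of 37.8% on average, gave p under 0.05. The share found there equalled the planted share by construction, because other clusters that met the second list were left out. With no X effect, 7% of 200 simulations gave p under 0.05, and a ratio of 1.25 was recovered as 1.25, with 91% of intervals holding it. The X simulations drew bins independently and did not carry the likeness of neighbouring bins. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.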

Results

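Clusters of chromatin immunoprecipitation signal were compared between 2 immunoprecipitated libraries of 1 cell line and with the list of the whole replicate set. The series has no treatment, so the comparisons are between replicates and between chromosomes. Enriched clusters of serine 2-phosphorylated RNA polymerase II covered 14.5% of the genome in replicate 1 and 15.4% in replicate 2 of the Clone 8 wing disc line (14.9 ± 0.668%, SD, n = 2). Replicate 1 held 5328 enriched clusters over 20.2 Mb and replicate 2 held 5170 over 21.5 Mb, with means of 5249 ± 112 clusters and 20.9 ± 0.934 Mb (SD, n = 2). The combined list held 5803 enriched clusters over 24.8 Mb, 17.8% of the genome. Each replicate list also held 1 cluster named as depleted, and the combined list held 23. Sequencing depth is unknown for these lists. The log2 enrichment of a cluster is the authors' own value throughout.

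Most clusters were a few kilobases wide, and a small number were far wider. The median width was 2546.5 bp in replicate 1, 2716 bp in replicate 2 and 2665 bp in the combined list. The widest clusters of the replicates measured 122222 and 122175 bp. Clusters wider than 20 kb numbered 46 in replicate 1 and 59 in replicate 2 (52.5 ± 9.19, SD, n = 2) and 90 in the combined list, where they held 11.5% of the covered length. The narrowest cluster measured 1301 bp in each replicate, and the combined list held 405 narrower ones. The median log2 enrichment was 0.97 in replicate 1 and 0.90 in replicate 2 (0.93 ± 0.05, SD, n = 2), and 0.76 in the combined list. Wider clusters had higher log2 enrichment, with a Spearman rho across clusters of 0.663, 0.658 and 0.643 in the 3 lists.

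The combined cluster with the highest score lay on X at 2210467 to 2212851 (FlyBase release 5, as are all positions here). Its log2 enrichment was 4.05 in the combined list, 4.52 in replicate 1 and 3.53 in replicate 2. The next lay on 3L at 11242795 to 11251214, a cluster of 8.42 kb with a log2 enrichment of 3.86 in the combined list and 3.61 and 4.03 in replicates 1 and 2. On 3R, the cluster at 8302070 to 8304528 reached 3.69 in the combined list and 4.03 in replicate 1, with a lower value in replicate 2. The cluster on 3L at 1585357 to 1587951 reached 3.60 in the combined list, and the one on 3L at 17555659 to 17558179 reached 3.59. A cluster on 2R at 19553216 to 19556339 also had a log2 enrichment of 3.59. The remaining 4 of the 10 highest clusters found in each replicate lay on 3R at 17121084 to 17133247 (3.54), 3L at 20941438 to 20944284 (3.45), 2L at 14408402 to 14410973 (3.44) and 3L at 8667799 to 8674685 (3.42). Of these 10, 5 lay on 3L, and 7 had a higher log2 enrichment in replicate 1 than in replicate 2. Their log2 enrichment ran from 3.38 to 4.52 in replicate 1 and from 3.16 to 4.03 in replicate 2.

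The widest combined cluster spanned 122.457 kb of 3L, from 22279915 to 22402371, and a single cluster of nearly the same span was present in each replicate. Its log2 enrichment was 1.58 in the combined list, 1.62 in replicate 1 and 1.54 in replicate 2. On 3R, 99.2 kb from 21340250 to 21439476 had a log2 enrichment of 1.19, and 92.8 kb from 4892255 to 4985094 had 1.00. The 96.2 kb cluster on 3L at 5147092 to 5243275 (0.99) was split into 6 clusters in replicate 1 and 5 in replicate 2. The fifth, 62.5 kb of chromosome 4 from 879019 to 941509 (0.91), was split into 8 clusters in replicate 1 and 3 in replicate 2.

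The density of clusters varied along every large arm in the same way in both replicates. Over 1203 bins of 100 kb on the 6 arms, the covered shares of the replicates had a Pearson correlation of 0.983 and a Spearman correlation of 0.985, across bins that are not independent replicates. By the mean of the replicates, the densest 500 kb bin was the first of 2L (1 to 500000), covered to 44.0% in replicate 1 and 44.9% in replicate 2. The next was 3R from 4500001 to 5000000, with 40.0% and 41.2%, followed by X from 15500001 to 16000000, with 35.4% and 37.2%. The lowest mean was on 2L from 14500001 to 15000000, with 1.31% and 0.861%. In replicate 1 the bin on 3L from 24000001 to 24500000 was lower, at 0.875%, with 1.87% in replicate 2.

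**Figure D1:**
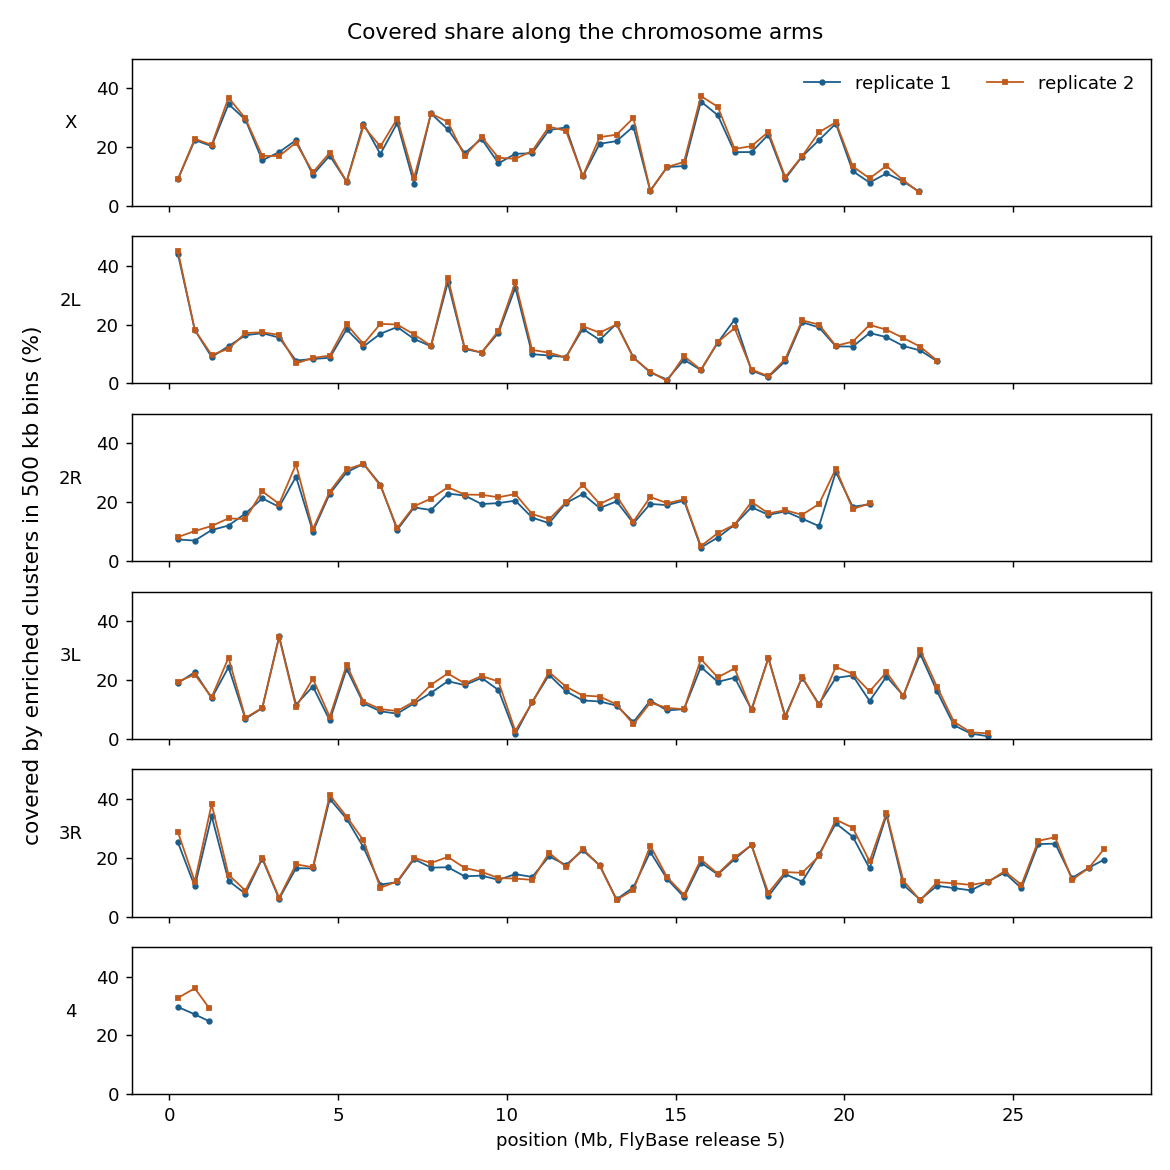
Percent of each 500 kb bin covered by enriched clusters (y axis) against position in Mb (x axis) for the 6 arms, with replicate 1 as circles and replicate 2 as squares. The replicates follow each other along each arm, and the first bin of 2L, at 44.0% and 44.9%, is the highest.

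Stretches longer than 100 kb with no enriched cluster in any of the 3 lists numbered 187 and made up 29.0 Mb, 24.1% of the 6 arms. They took 31.6% of 2L, 25.4% of 3L, 24.2% of 3R, 22.8% of X and 17.4% of 2R, and chromosome 4 had none. The longest lay on 3L from 24031410 to 24529541 (498 kb), near the centromeric end of the arm, and on 2L from 16911235 to 17382891 (472 kb). The proximal 1 Mb, taken at the centromeric end of each arm sequence, was covered to 2.30% on 3L, 7.51% on X, 8.17% on 2R and 9.53% on 2L (means of 2 replicates). These shares lay below the rest of the same arm in each replicate. The heterochromatic sequences are separate from the arm sequences, so distance to the centromere is not known and may differ between arms. The rest of these arms was covered to 16.1%, 19.8%, 18.8% and 14.6%. On 3R the order was the other way, with 19.0% in the proximal 1 Mb and 17.3% in the rest. Whether reads could be aligned throughout these stretches was not examined, so absence of clusters need not mean absence of polymerase.

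X, present in 1 copy in males, was compared with the autosomal arms by covered share, as the line is labelled male. X was covered to 19.3%, 2R to 18.3%, 3R to 17.3%, 3L to 15.5% and 2L to 14.4% (SDs of 0.638, 0.965, 0.710, 0.682 and 0.518, n = 2). Over 100 kb bins, 19.3% of X and 16.4% of the autosomal arms were covered, a ratio of 1.18 (bootstrap interval 1.04 to 1.33; permutation p = 0.0079, two-sided, 224 X bins and 965 autosomal bins). The ratio was 1.19 in replicate 1 and 1.17 in replicate 2. When the X block was instead moved along the joined arms, which keeps neighbouring bins together, a difference as large appeared in a share of 0.156 of 1189 rotations. The difference was thus not shown to exceed the variation along the chromosomes. The block holds 224 of the 1189 bins, and many rotations overlap X itself, so this test could hardly give a small share and leaves the question open. X exceeded 2R by 0.952 ± 0.328 percentage points (SD, n = 2).

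X clusters also had a higher median log2 enrichment than autosomal ones in each replicate. The medians were 1.09 on X and 0.94 on autosomal arms in replicate 1 (difference 0.15), and 0.99 and 0.87 in replicate 2 (difference 0.12). In a two-sided permutation test over clusters (10000 permutations), p was 0.0001 in both, the smallest it can give, and 0.00015 after Benjamini-Hochberg adjustment over 3 lists. In the combined list the medians were 0.78 and 0.74, a difference of 0.03 that did not pass the permutation test (p = 0.29, adjusted 0.29). The 90th percentile of log2 enrichment was not higher on X: it was 2.16 on X and 2.19 on autosomal arms in replicate 1, 1.93 and 1.94 in replicate 2, and 1.85 and 1.94 in the combined list. Clusters are not replicates, and these p-values treat them as independent.

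Chromosome 4, a small and largely heterochromatic autosome, had the highest covered share of all sequences, at 27.5% in replicate 1 and 33.0% in replicate 2 (30.3 ± 3.94%, SD, n = 2). This was 1.84 ± 0.16 times the share of the autosomal arms. It held 62.5 ± 0.523 clusters per Mb against 41.5 ± 0.812 on the autosomal arms, and its median log2 enrichment was 0.80 ± 0.06 against 0.91 ± 0.05 (SD, n = 2). Its highest combined cluster lay at 1296157 to 1298638, with a log2 enrichment of 2.81 in the combined list, 3.19 in replicate 1 and 2.36 in replicate 2. With 2 replicates and 1 such chromosome no test was made.

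The mapped heterochromatic sequences were covered to 2.02 ± 0.435% and the unplaced sequence U to 1.25 ± 0.0853% (SD, n = 2), which is 0.123 ± 0.0212 and 0.0761 ± 0.00189 times the autosomal arms. Both lay below every arm in each replicate. Among them 2LHet had 5.40%, XHet 3.68%, 3LHet 2.44%, 2RHet 2.26% and 3RHet 0.926%. The order rests on few clusters, as 2LHet held 6 and 5 and XHet 2 and 3 in replicates 1 and 2. The highest combined cluster of the sequence was found in each replicate on 2LHet, from 123207 to 125880 (2.47), and on 3LHet, from 2396709 to 2402975 (2.33). The same held on 3RHet, at 1704316 to 1707013 (1.33), and on XHet, at 74258 to 79768 (0.87). On U it was in neither replicate. The highest replicate 2 cluster on U, at 3.78, did overlap a replicate 1 cluster, since no replicate 2 cluster without such an overlap exceeded 2.31. No cluster lay on YHet in either replicate, and the combined list held 2 there. Clusters on U, 45 in replicate 1 and 46 in replicate 2, had a median log2 enrichment of 1.49 ± 0.143, above the 0.91 ± 0.05 of the autosomal arms. Scores on U were not all repeated, as the 2 highest replicate 1 clusters without an overlap in replicate 2 lay there. As the alignable part of the heterochromatic and unplaced sequences was not examined, their low covered shares need not mean little polymerase.

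**Figure D2:**
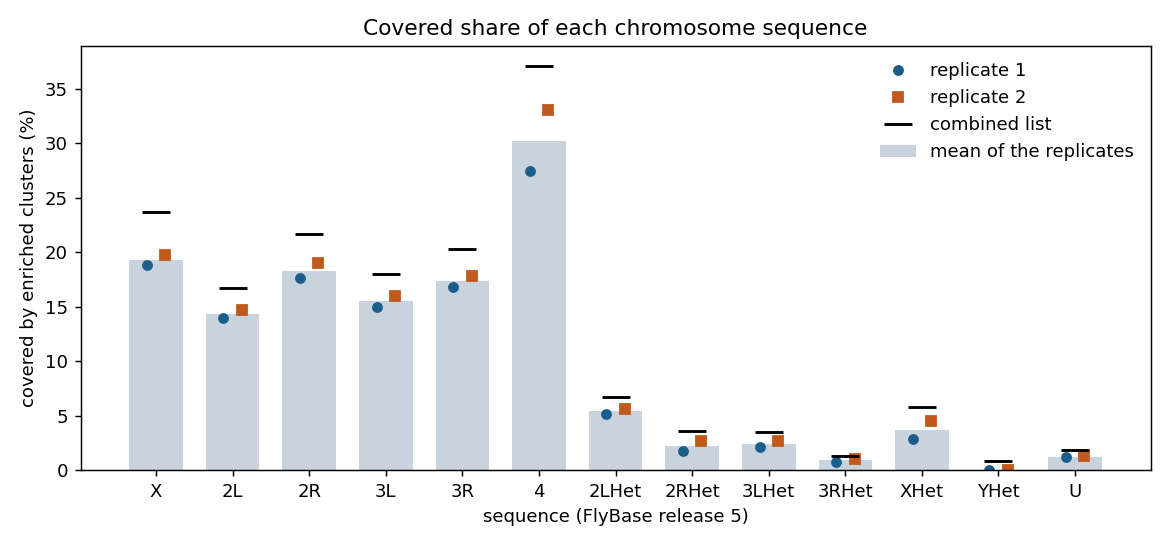
Percent of each sequence covered by enriched clusters (y axis) for the 13 sequences (x axis), with bars at the mean of the replicates, circles and squares for replicates 1 and 2, and dashes for the combined list. Chromosome 4 stands highest at 27.5% and 33.0%, and the heterochromatic and unplaced sequences lie below all arms.

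The replicates placed their clusters at the same positions far more often than shifted lists did. Of the replicate 1 clusters, 4914 of 5328 (92.2%, exact binomial interval 91.5 to 92.9%) overlapped a replicate 2 cluster, against a mean of 28.4% and a highest value of 38.4% over 1000 circular shifts (permutation p = 0.001, the smallest they can give). Of the replicate 2 clusters, 4649 of 5170 (89.9%, 89.1 to 90.7%) overlapped a replicate 1 cluster, against 28.6% and 41.0% (p = 0.001, permutation). The Jaccard index of covered bases was 81.4%, against 9.37% and 13.5% (p = 0.001, permutation). Shared bases came to 18.7 Mb, 92.7% of the length in replicate 1 and 87.0% of that in replicate 2. There were 386 replicate 2 clusters that overlapped more than 1 replicate 1 cluster, and 162 in the other direction.

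Clusters without a counterpart were mostly narrow and weak. The 414 of replicate 1 had a median width of 1734 bp and a median log2 enrichment of 0.46, and the 521 of replicate 2 had 1707 bp and 0.50. In the lowest quartile of log2 enrichment, 75.7% of replicate 1 and 71.4% of replicate 2 clusters were shared, and in the highest quartile 99.5% and 99.3%. The highest-scoring exceptions in replicate 1 lay on U, at 9733428 to 9735326 (3.61) and 8870024 to 8872038 (3.18). Those in replicate 2 lay on 2R at 4506 to 5968 and on 3L at 21236827 to 21238175, both with 2.31. Each of these 4 overlapped a combined cluster of lower log2 enrichment, at 2.16, 2.72, 1.35 and 1.33.

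**Figure D3:**
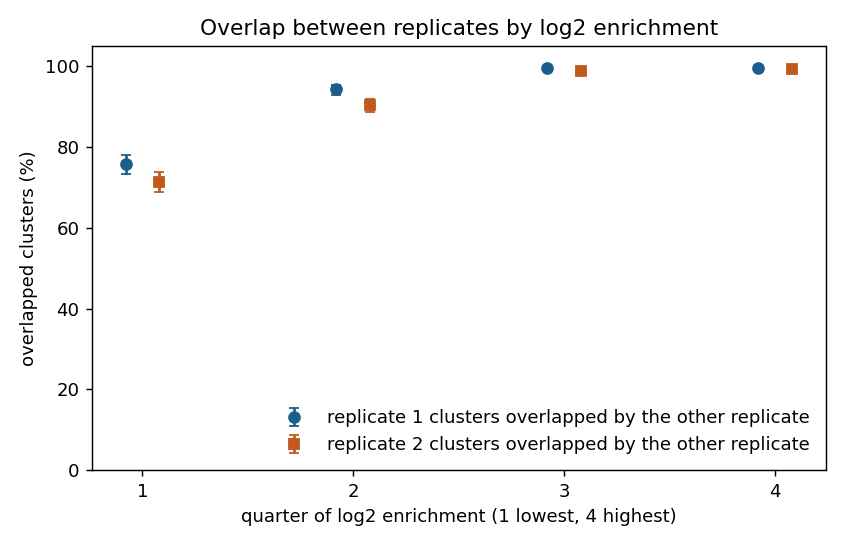
Percent of clusters that overlapped a cluster of the other replicate (y axis) by quartile of log2 enrichment within each list (x axis), with exact 95% binomial intervals. Sharing was 75.7% and 71.4% in the lowest quartile and 99.5% and 99.3% in the highest.

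Across 4533 mutual best pairs, log2 enrichment had a Pearson correlation of 0.922 and a Spearman correlation of 0.907, and cluster widths a Spearman correlation of 0.867. These are correlations across clusters of 2 libraries. Replicate 2 had the lower value in 66.9% of pairs, with a mean difference (replicate 2 minus replicate 1) of -0.12 ± 0.27 (SD over pairs). The difference was -0.07 in the lowest quartile of mean log2 enrichment and -0.27 in the highest.

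Of the 5803 combined clusters, 4296 (74.0%, exact binomial interval 72.9 to 75.2%) overlapped clusters of both replicates and held 89.6% of the combined length. A further 357 overlapped replicate 1 only and 445 replicate 2 only. The remaining 705 (12.1%, 11.3 to 13.0%) overlapped neither. Those 705 had a median width of 1296 bp and a median log2 enrichment of 0.37, against 3456.5 bp and 0.98 for clusters found in both. A combined cluster was overlapped by 99.4% of replicate 1 and 99.6% of replicate 2 clusters. On 5 sequences the highest-scoring combined cluster was in neither replicate. These were 3R at 4724054 to 4725606 (3.72), 2L at 19353847 to 19354848 (3.50), 2RHet at 3241479 to 3242494 (3.37), U at 9974249 to 9975426 (3.23, the widest of 4 clusters with this value, none of them in a replicate) and YHet at 71786 to 72859 (1.50), all between 1.00 and 1.55 kb wide.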

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

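The tests of the depleted clusters were chosen after the result was seen.

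The combined list named 23 clusters as depleted, a signal outside the comparisons of enriched clusters, where each replicate list had 1. They lay on 2L, 2R, 3L, 3R and X, were 1656 to 1876 bp wide and had log2 values from -0.11 to -0.0013, close to 0. At 16 of the 23 places a replicate had a cluster named as enriched, in replicate 1 at all 16 and in replicate 2 at 4 of them. The replicate 1 clusters there had log2 values of 0.08 to 0.39, against an SD of 0.18 between replicates for the weakest quartile of paired clusters. At 12 of the 16 places replicate 2 had no cluster, and at the other 4 its clusters had values of 0.24, 0.10, 0.12 and 0.12. Every depleted cluster had a value below 0 and every enriched one above 0 in the 3 lists. A name that followed the sign of the score, on clusters called by another criterion, and signal below input in both libraries cannot be told apart here. The 16 overlaps do not decide, because the replicate lists hold 1 depleted cluster each, so that nearly any cluster met is an enriched one, and the combined list covers the same replicates. What the score is relative to is also not stated in the sources used here, so a value above 0 need not mean signal above input. No biological explanation was tested, as the design gives no group for it.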

How the results depend on the processing

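Of 35 alternatives over 10 results, 26 kept their direction and side of the threshold or moved by less than the spread, 8 moved and 1 no longer passed. The rotation of the X block, the removal of clusters wider than 20 kb, the minimum width of combined clusters, the removal of the widest chromosome 4 cluster and the covered length of single replicates were chosen after seeing the data. For X against autosomes the ratio stayed at 1.18 under the rotation, but the p rose to 0.156. That test keeps neighbouring bins together, which the permutation of bins does not. With the upper 50% of clusters by score, the ratio of X to autosomes was 1.36 (p = 1e-05, permutation of bins). That cut favours X, whose clusters had the higher median score in each replicate. The ratio was between 1.17 and 1.24 under the other settings, with p from 0.00028 to 0.03 by permutation of bins, and 1.17 to 1.19 with a replicate left out. The overlap of the replicates stayed past its threshold under each alternative, with 80.6% and 83.1% for replicates 1 and 2 when 50% of each cluster had to be covered reciprocally (100 shifts, smallest p 0.0099). Under that rule Spearman's rho rose to 0.912 for scores and 0.914 for widths, and combined clusters shared with both replicates fell to 66.9%. Combined clusters at least 1301 bp wide were shared with both replicates at 79.6%. The shares that overlapped replicate 1, or replicate 2, whatever the other held, were 80.2% and 81.7%. That looser rule cannot give less than the 74.0% for both, so these 2 alternatives, counted among the 8 that moved, say nothing of stability. Keeping the upper 50% of clusters by score cut the covered length to 14.2 Mb and the ratio of heterochromatic sequences to autosomal arms to 0.0875. The shorter length follows from fewer clusters, and the cause of the lower ratio was not tested. The chromosome 4 ratio was 1.78 under that setting and 1.68 without the widest chromosome 4 cluster of each list. With a replicate left out, the covered length was 20.2 to 21.5 Mb, the chromosome 4 ratio 1.73 to 1.96 and the heterochromatic ratio 0.108 to 0.138. With 2 replicates a single one always lies within 1 SD of their mean, so these ranges say nothing of stability. They are counted among the 26 above, where they carry no weight.

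No paired analysis was possible because no result compares immunoprecipitations with inputs, although they share replicate numbers. Each cluster analysed here carries a single score, with no input value beside it to pair. A further 15 alternatives on genes, chosen before the data were examined, were not run, for want of an annotation of the same release. Depth is unknown, so what it limits cannot be stated.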

Other observations

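Of the tests below, those of unshared clusters on X and of bases covered in both replicates had their criteria written before their values were seen. All others in this part were chosen after the results were seen, and the bounds that decide them were set then too.

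Each replicate list had 1 depleted cluster. That of replicate 1 lay on 3L from 12460481 to 12462170 (-0.03) and met no cluster elsewhere. That of replicate 2 lay on chromosome 4 from 424228 to 425922 (-0.0002), where replicate 1 had an enriched cluster of 0.35.

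The higher covered share of X may come from where dense regions lie along the chromosomes. Moving the X block along the joined arms gave a difference as large in a share of 0.156 of rotations, so this stays open. A few very wide clusters are argued against, since the ratio was 1.19 (bootstrap interval 1.0502 to 1.34) without clusters wider than 20 kb, and so are clusters of a single replicate, since the ratio over bases covered in both was 1.16 (1.02 to 1.31), though both intervals treat bins as independent. Chance clusters from fewer reads on a single X stay open for a part. Unshared clusters were 9.36% on X and 7.30% on autosomal arms in replicate 1 and 10.4% and 9.53% in replicate 2, a mean excess of 1.46 points with overlapping binomial intervals, and no biological explanation was tested, as the series has no other group.

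Among the 705 combined clusters found in neither replicate, the smaller minimum width cannot be the whole cause, since 50.4% (exact binomial interval 46.6 to 54.1%) were narrower than 1301 bp and 350 were not. Weaker enrichment reached by pooling stays open, because their median log2 enrichment of 0.37 lay below the lower quartile of clusters found in both, 0.63, but above the median of those found in 1 replicate, 0.33. The strongest of them may instead rest on small numbers. If scores are read as ratios of whole numbers (next paragraph), the numbers summed to 50 or less in 13.8% (11.3 to 16.5%) of them against 5.24% (3.80 to 7.01%) of those found in 1 replicate and 1.44% (1.11 to 1.85%) of those found in both, and in all 24 with a log2 enrichment above 2. The cluster on 3R at 4724054 to 4725606 corresponds to 14 over 1 and that on 2L at 19353847 to 19354848 to 12 over 1, in lowest terms, so the underlying numbers could be larger. If the numbers are counts over a cluster they also grow with its width, and clusters found in neither replicate were the narrower. No comparison at matched width was made. The median sum per kb was 285 in clusters found in neither replicate, 354 in those found in 1 and 599 in those found in both.

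A hypothesis on the form of the scores is that each is the base-2 logarithm of a ratio of whole numbers times 1 constant per list. Several starting constants and size limits were tried, and the one giving the smallest terms was kept. With factors of 0.940, 0.942 and 0.941 for replicates 1 and 2 and the combined list, all scores of the replicates and 99.966% of those of the combined list (all but 2) were met within 1e-12 by denominators up to 20000. After random shifts of up to a millionth, at most 0.0563% were met in any list. In simulated lists of 3000 scores the method recovered 100% of known ratios and matched 0.1% of random scores. Nothing in the sources used here states this, and no interval for a score was drawn from these numbers, as the binomial intervals above cover counting over clusters only.

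If so, the denominators may be input reads, and they would carry the copy number of X. The upper quartile of denominators per kb on X was 0.511, 0.538 and 0.520 of that on the autosomal arms in replicates 1 and 2 and the combined list (mean 0.523), while chromosome 4 had 1.02 to 1.12. The numerators per kb on X were likewise 0.541, 0.579 and 0.532 of those on the autosomal arms. A line with 1 X for each autosome pair could give such values in both terms, so they do not mark the denominators as input. Copy number would then largely cancel in the score, but all these terms come from called enriched clusters. Values in lowest terms understate the true numbers, and this was not tested against reads. The combined list may have been scored on summed reads, as its denominators per kb on the autosomal arms were 0.980 of the sum over the replicates.

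The higher median log2 enrichment on X in single replicates may reflect weak X clusters that were not called with fewer reads. The excess fell from 0.15 and 0.12 in the replicates to 0.035 in the combined list. It was larger at the lower quartile (0.16 and 0.15) than at the upper (0.07 and 0.05) in replicates 1 and 2, and at the upper quartile of the combined list it was -0.007. The medians had been seen before this test was written, and a difference in polymerase between X and autosomes was not separated from it.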
